A study of Homo sapiens with 6 samples.

How the data were processed

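Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map H3K4me3 and H3K27me3 in H1299 cells, an established human non-small cell lung cancer line, grown with or without 5 mM metformin. H3K4me3 is the trimethylated form of histone H3 lysine 4, found mainly at active promoters, and H3K27me3 is the Polycomb-deposited trimethylation of lysine 27. Per the labels' protocols, chromatin was cross-linked with formaldehyde and cut with micrococcal nuclease, and the fragments were precipitated with an antibody against each mark. The series holds 6 samples: 1 library for each mark and condition, and 1 input library for each condition. The peak lists of the 4 ChIP libraries were analysed, and the 2 input libraries were not analysed here.

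Per the labels, each list belongs to 1 library, so samples were not pooled. The submitters' processing notes name Trimmomatic 0.38, Bowtie and MACS2, and the build hg19 (GRCh37). The options of each step, and which library served as background, are not given in the sources used here. Each list gives a chromosome, a start, an end, a name and 1 value per line, with no header. The deposited value was read as a −log10 q from the values themselves. In the H3K4me3 lists the smallest values, 1.31 in both, lie just above the −log10 of q = 0.05, which is 1.30. The 8 most frequent values of the control list climb from 3.57 to 11.3 in steps that widen from 0.983 to 1.22, as tail probabilities of whole read pileups do. In the H3K27me3 lists the values start just above 1, at 1.01 and 1.00, which is the −log10 of q = 0.1, the usual limit of MACS2's broad mode. MACS2 gives a broad region the average over its length, and 99.6% of the values in both H3K27me3 lists were under 3. These values were used to describe, rank or filter intervals within a list. Their length-weighted means are printed beside ratios of covered length, and their medians per bin within the control H3K4me3 list entered 1 test of DNA copy number. They are not signal levels, and higher values in 1 condition were not read as a stronger mark.

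Lines that share an interval (lettered sub-peaks of H3K4me3) were joined into 1 interval that carries its highest value. No intervals within a list overlapped after that step. Coordinates are given 1-based on hg19. For each mark, an interval counted as shared if at least 1 bp of it was overlapped by the other condition's list. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. As a chance level, 1 list was moved along each chromosome by a random offset, 100 times. H3K4me3 intervals of 4 kb or more were counted as broad domains. Covered length was also summed in 1 Mb bins. Read depth is unknown, since the lists hold no counts. Code for the overlaps was tested on simulated data: the control list of each mark was thinned at random and moved by a fixed short distance, and 100% of the kept intervals were recovered with 0% false overlaps, for 50585 H3K4me3 and 85579 H3K27me3 intervals. Overlap counts equalled those of bedtools 2.31.1 in the 3 pairs of lists tried. The analysis used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

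There was 1 library per mark and condition, so no test between conditions could be made and no p-value is given. The comparisons, their alternatives and the rule for named regions were fixed before the data were examined. The rule names the 5 intervals with the highest −log10 q of each list, and the 5 per list with the highest −log10 q among those the other list did not overlap. It was written for fold enrichment, and −log10 q took its place because the lists hold 1 value. Regions named outside the rule are said to have been chosen after their values were seen. The overlap of the 2 marks with each other replaced a planned count of promoters with both marks. It was added after seeing the data, as were the comparisons by chromosome and bin and the shared length by width. Counts of promoters, the location of intervals relative to genes, and 17 gene lists with 458 genes (cell cycle, AMPK signalling, metabolism, chromatin regulators, lineage and other cell type markers) had been planned. They were not analysed here, because the gene table at hand is on GRCh38.p14 and the lists are on hg19, per the submitters' processing notes. Positions were not converted between builds.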

Results

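The study examined H3K4me3 and H3K27me3 in H1299 lung cancer cells with and without 5 mM metformin, a biguanide used against type 2 diabetes. The 4 ChIP libraries analysed were 1 control and 1 metformin library for each mark, so the values below have no replicate error. H3K4me3 was called as 50585 intervals in control cells and 53454 in metformin-treated cells. H3K27me3 was called as 85579 and 85952 intervals. At a −log10 q of 5 or more, 28139 and 30403 H3K4me3 intervals and 16 and 11 H3K27me3 intervals were left. Depth per library was unknown, because the peak lists hold no read counts, and a longer list can come from a deeper library. The values are those deposited for each peak, and their reading as −log10 q is inferred. For H3K4me3 the value is that of the highest sub-peak and for H3K27me3 it was taken as an average over the region. The limit of 5 therefore does not compare the marks.

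Both marks covered more sequence in the metformin libraries. H3K4me3 intervals covered 49.4 Mb in control cells and 55.2 Mb after metformin, which is 1.12 times as much, at length-weighted mean −log10 q values of 25.5 and 30.3. H3K27me3 intervals covered 85.5 Mb and 93.3 Mb, 1.09 times as much, at 1.67 and 1.68. For H3K4me3 the larger coverage came with both more intervals (1.06 times) and a larger mean width, 977 bp in control and 1032 bp after metformin. For H3K27me3 the number of intervals was nearly equal (1.00 times) and the mean width was 999 bp against 1085 bp. The shortest H3K27me3 interval was 159 bp in control and 166 bp after metformin, and the smallest gap between intervals was 642 and 670 bp. In the H3K4me3 lists these were 162 and 165 bp in both conditions. The H3K27me3 lists may thus have been called with different lengths. With intervals within 1 kb merged, which exceeds both smallest gaps, H3K27me3 covered 98.9 Mb in control and 106.5 Mb after metformin. The merged intervals numbered 68834 and 69775. Unequal joining alone therefore does not account for the larger coverage, and other effects of different lengths were not tested.

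H3K4me3 sites were largely held in common. Of the control intervals, 77.3% (39117 of 50585, 95% interval 77.0 to 77.7) overlapped a metformin interval, and of the metformin intervals 67.3% (35955 of 53454, 66.9 to 67.7) overlapped a control interval. Random placement gave a median of 3.44% of control intervals. The shared sequence was 41.0 Mb, or 83.0% of the control and 74.3% of the metformin covered length. Metformin-only intervals numbered 17499, against 11468 control-only intervals.

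H3K4me3 intervals with high values or large widths had partners in the other list. Among control intervals with a −log10 q of 50 or more, 1659 of 1659 were overlapped by the metformin list, and so were 3133 of 3133 such metformin intervals by the control list. From 20 upwards, 1 of 11281 control and 15 of 14056 metformin intervals lacked a partner. At −log10 q values under 2, 41.0% of control intervals and 27.5% of metformin intervals had one. Intervals found in a single list were short: the median width was 252 bp for control-only and 263 bp for metformin-only intervals, against 742 bp and 954 bp for the shared ones. All 7403 control intervals of 2 kb or more had a metformin partner. Of the 8772 such metformin intervals, 1 had no control partner, at chr3:48080069-48082259, which was named after its values were seen. It is 2191 bp long and held 5 sub-peaks with a −log10 q of up to 7.88.

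**Figure D1:**
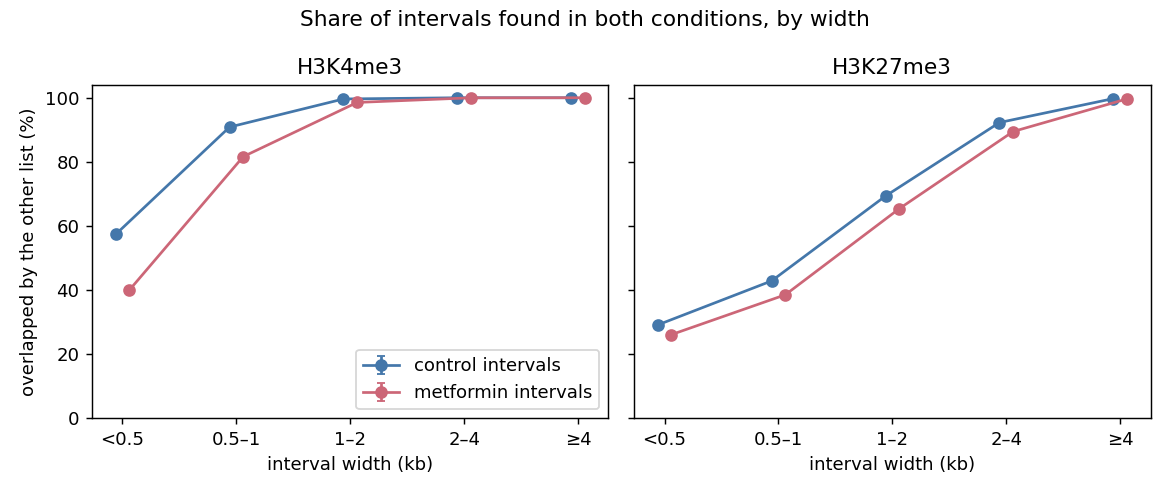
Share of H3K4me3 (left) and H3K27me3 (right) intervals overlapped by at least 1 bp of the other condition's list, in percent, by interval width in kb; points are shares, bars are 95% exact binomial intervals (mostly smaller than the points), and lines join the width classes. H3K4me3 intervals of 1 kb or more were shared at 98.5% or above in each class, while H3K27me3 intervals came to 99.7% (control) and 99.6% (metformin) only from 4 kb upwards.

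Of the 5 H3K4me3 intervals with the highest values, 3 lay on chromosome 19 in each list. The control list was led by chr19:39922727-39928123 (−log10 q 151) and chr19:37708022-37711053 (149), followed by chr14:102546531-102552959 (144), chr12:46117551-46124084 (141) and chr19:37567953-37571744 (135). The metformin list was led by chr19:37567510-37571798 (159), which is the fifth of the control list, and chr19:39138300-39144617 (148). After these came chr19:40949304-40952141 (147), chr1:16937691-16941395 (140) and chr1:143466759-143467644 (140). Each of these 10 intervals had a partner in the other list. None of them was overlapped by H3K27me3 of its own condition.

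The highest-valued H3K4me3 intervals of a single list had lower values, and most lay close to an interval of the other list. Among metformin-only intervals these were chr16:50775275-50775638 (−log10 q 30.4), chr3:52091537-52092433 (29.4), chr20:47805137-47805740 (27.5), chr9:35791738-35792015 (23.1) and chr3:195474935-195475265 (22.9). The first of them lay 30 bp from the nearest control interval, the next 3 lay 268, 312 and 220 bp away, and the fifth lay 88.8 kb away. Among control-only intervals they were chr1:155990846-155991207 (20.6), chr9:45354124-45354313 (17.5), chr14:97263281-97263513 (15.7), chr7:74989763-74990014 (15.1) and chr1:32816595-32817026 (14.8). Distances to the nearest metformin interval were 141 bp, 2.35 kb, 408 bp, 80.0 kb and 46 bp.

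Broad H3K4me3 domains of 4 kb or more were more numerous after metformin, 1595 against 1236 in control cells (1.29 times). With a limit of 2 kb the numbers were 8772 and 7403, and with intervals within 1 kb merged first they were 6778 and 5627. Of the control domains, 845 (68.4%, 95% interval 65.7 to 71.0) were overlapped by a metformin domain, and 845 of the metformin domains (53.0%, 50.5 to 55.5) by a control domain. The 750 domains that were broad only after metformin were not new sites: none lacked control H3K4me3, and a median of 86.1% of their length was covered by shorter control intervals. The 391 domains broad only in control cells were covered to a median of 88.4% by metformin intervals. The longest domain was the same in both, chr3:98606231-98620522 in control (14.3 kb) and chr3:98606102-98620553 after metformin (14.5 kb). Other long domains, named after their values were seen, were chr6:30647025-30660109 (13.1 kb in control, 12.9 kb after metformin) and chr7:99094791-99106744. The latter was 11954 bp long after metformin and was overlapped by 6 control intervals of at most 5833 bp. Where 1 control interval matched 1 metformin interval, which held for 21768 pairs of any width, the metformin interval was the wider in 60.6% of pairs that differed, with a median ratio of 1.06. In the 3549 pairs with a mean width of 2 kb or more the difference was smaller, with 56.3% wider and a median ratio of 1.02.

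H3K27me3 intervals were shared less often, but 99.6% of their values in both lists were under 3, close to the inferred calling limit. Of the control intervals, 48.3% (41334 of 85579, 95% interval 48.0 to 48.6) overlapped a metformin interval, and 46.3% (39806 of 85952, 46.0 to 46.6) of the metformin intervals overlapped a control interval, against a median of 5.85% of control intervals under random placement. When at least 50% of an interval had to be overlapped, the shares were 29.9% and 26.1%, and for intervals of 2 kb or more with the 1 bp rule they were 94.1% and 92.2%. The shared sequence was 36.9 Mb, or 43.1% of the control and 39.5% of the metformin covered length. Under 500 bp, 29.1% of control and 26.1% of metformin intervals were overlapped, and from 4 kb upwards 99.7% (2293 of 2299) and 99.6% (2843 of 2853). A wide interval is touched more easily, with chance levels of 4.22% and 13.3% for those classes of control intervals. The share of covered length, whose chance level hardly depends on width (3.31% and 3.35% in control), was 22.9% in control and 19.98% after metformin under 500 bp. From 4 kb upwards it was 71.6% and 66.0%, so part of the length was not shared even in the widest class. The single-list intervals were mostly short, with median widths of 481 bp (control) and 514 bp (metformin). At low values H3K4me3 was also shared less, at 41.0% in control and 27.5% after metformin under 2. H3K27me3 sharing was 40.1% and 41.5% at values from 1.3 to 1.5, and 56.7% and 55.7% from 1.5 to 2. The values are defined differently for the marks, so these classes do not match the marks. The lower H3K27me3 share was therefore not read as a larger change of that mark.

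The longest H3K27me3 regions, named after their values were seen, lay on chromosomes 12 and 19. In control cells chr19:41959892-41994675 was the longest (34784 bp), and its metformin counterpart was 34832 bp long. After metformin the longest was chr12:4296223-4345333 (49.1 kb), where the control list held 6 intervals of at most 19976 bp that covered 87.9% of it. The region chr19:42000532-42046909 was 46.4 kb long after metformin, and the control list held 4 intervals there, the longest of 30.3 kb. Other long regions were divided after metformin instead. The control regions chr19:30059111-30089676 (30.6 kb), chr12:53058333-53088875 (30.5 kb) and chr19:40046710-40077159 (30450 bp) were overlapped by 3, 4 and 3 metformin intervals, the longest of 16.1, 15.8 and 22.3 kb. In the 200 kb window from 4.25 to 4.45 Mb on chromosome 12, H3K27me3 covered 127 kb in 38 control intervals and 141 kb in 32 metformin intervals.

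**Figure D2:**
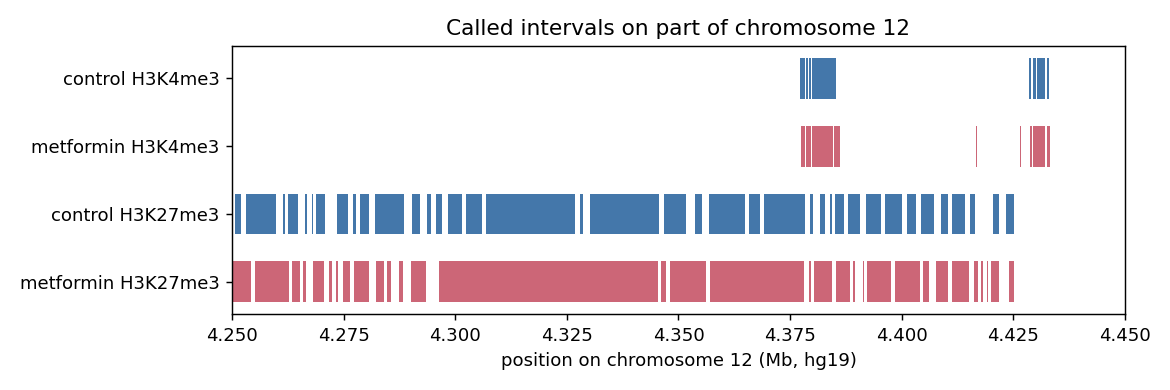
Called intervals of the 4 lists from 4.25 to 4.45 Mb of chromosome 12 (hg19, position in Mb); each box is 1 interval drawn to scale, blue for control and red for metformin. H3K27me3 spans most of the window in both conditions and is joined into a 49.1 kb region after metformin, and the H3K4me3 block at chr12:4380000-4384624, to the right of that region, is present in both conditions.

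The highest H3K27me3 values came from a single stretch of chromosome 2. All 5 of the highest control regions, from chr2:92307276-92307493 (−log10 q 53.0) to chr2:92323152-92325922 (19.1), and 4 of the 5 highest metformin regions lay there. The fifth metformin region was chr21:9698915-9699681 (11.1). Of all H3K27me3 regions with a value of 5 or more, 8 of 16 in control and 6 of 11 after metformin lay between 92 and 93 Mb of chromosome 2. The input libraries were not analysed, so whether the input was also high there is unknown. These values were not read as the strongest H3K27me3 sites. The single-list regions with the highest values were 160 to 277 bp long, apart from the first control region of 1318 bp. In control they were chr2:92290877-92292194 (9.64), chr19:8890298-8890457 (6.08), chr12:70161-70347 (6.01), chr19:8878696-8878867 (5.58) and chr2:90454333-90454531 (5.12). After metformin they were chr1:143280369-143280552 (4.81), chr15:75566982-75567171 (4.53), chr8:46849943-46850126 (4.33), chr3:185969098-185969283 (4.23) and chr2:86460670-86460946 (4.20).

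Coverage was larger after metformin on each of 23 chromosomes (1 to 22 and X) for both marks, by unequal amounts. For H3K4me3 the metformin to control ratio of covered length ran from 1.06 on chromosome 6 to 1.23 on chromosome 22, with a median of 1.12. For H3K27me3 it ran from 1.01 on chromosome 18 to 1.22 on chromosome 22, with a median of 1.10. Across 1 Mb bins the order of covered length was nearly the same in both conditions (Spearman rho 0.99 for H3K4me3 over 2528 bins and 0.98 for H3K27me3 over 2211 bins, where bins are not replicates). The densest H3K4me3 bin, 27 to 28 Mb of chromosome 6, held 179 kb in control and 196 kb after metformin. Bins with the largest differences were named after their values were seen. H3K4me3 covered 122 kb in control and 165 kb after metformin between 1 and 2 Mb of chromosome 19, and 67.3 kb and 56.6 kb between 66 and 67 Mb of chromosome 12. H3K27me3 covered 202 kb and 266 kb between 102 and 103 Mb of chromosome 10, and 259 kb and 220 kb between 10 and 11 Mb of chromosome 18. The densest H3K27me3 bin, 2 to 3 Mb of chromosome 12, held 615 kb in control and 612 kb after metformin.

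**Figure D3:**
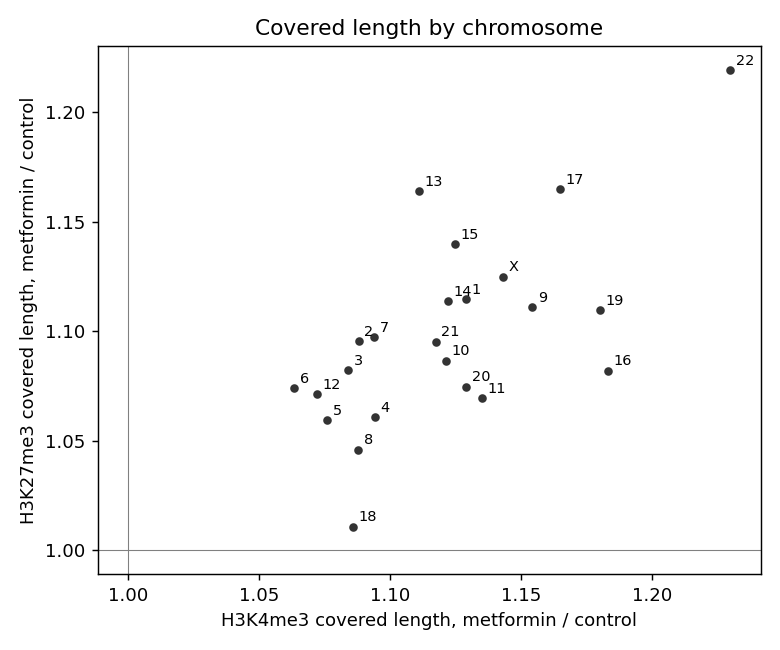
Ratio of covered length, metformin over control, for H3K4me3 (horizontal) and H3K27me3 (vertical), with 1 point per chromosome (1 to 22 and X) and grey lines at a ratio of 1 (1 library per mark and condition, so no error bars). All chromosomes lie above 1 on both axes, and chromosome 22 is highest for both marks, at 1.23 and 1.22.

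The 2 marks seldom met on the same sequence, and they met more often in the metformin lists. In control cells 1408 of 50585 H3K4me3 intervals (2.78%, 95% interval 2.64 to 2.93) were overlapped by H3K27me3, and after metformin 2432 of 53454 (4.55%, 4.37 to 4.73). Among H3K4me3 intervals with a −log10 q of 5 or more the numbers were 652 and 1259. The sequence covered by both was 0.514 Mb in control and 1.08 Mb after metformin, 2.11 times as much. Random placement gave medians of 1.51 Mb and 1.87 Mb, so both values lay below chance. With control H3K4me3 kept and the metformin H3K27me3 list put in place of the control list, 0.690 Mb was covered by both. With the lists exchanged the other way it was 0.738 Mb. Of the 2432 intervals with both marks after metformin, 796 also had both in control cells, 635 had H3K4me3 alone, 490 had H3K27me3 alone and 511 had neither. Of the 1408 intervals with both marks in control cells, 763 (54.2%) also had both after metformin, 324 had H3K4me3 alone, 187 had H3K27me3 alone and 134 (9.52%) had neither.

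Regions with the longest overlap of the marks were named after their values were seen. After metformin, chr2:136872431-136877421 carried H3K4me3 over 4991 bp, 4265 bp of it under H3K27me3. The control lists held 3995 bp of H3K4me3 and 2337 bp of H3K27me3 there. The H3K4me3 interval chr1:152079692-152084333 was under H3K27me3 over 3699 bp after metformin and over 50 bp in control cells. On chromosome 12, chr12:4380000-4384624 was under H3K27me3 over 4075 bp after metformin and over 2097 bp in control. In control cells the longest was chr11:109293001-109295721, with 2364 bp under H3K27me3 against 916 bp after metformin. Within each list, H3K4me3 intervals with a −log10 q of 50 or more carried H3K27me3 least often, 5 of 1659 in control (0.301%) and 30 of 3133 after metformin (0.958%). The same limit picks different sets of intervals in the lists, so these shares do not compare the conditions.

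**Figure D4:**
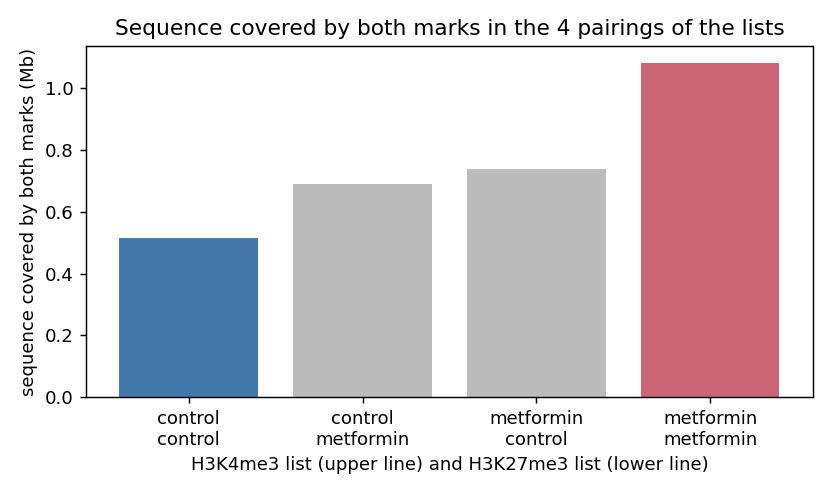
Sequence covered by both H3K4me3 and H3K27me3, in Mb, for the 4 pairings of the control and metformin lists; each bar is 1 pairing and has no error bar, since there was 1 library per mark and condition. The pairing within control cells gave 0.514 Mb, the mixed pairings (grey) 0.690 and 0.738 Mb, and the pairing within metformin-treated cells 1.08 Mb.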

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

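No replicate could be left out and no paired analysis was possible because there was 1 library per mark and condition. The planned counts of promoters, gene lists and locations relative to genes were not run, for want of gene positions on hg19. H3K27me3 sharing at 1.5 or more and at 2 kb or more, the exclusion of 92 to 93 Mb of chromosome 2, coverage at equal list length and the settings for the overlap of the marks were chosen after seeing the data. Shares below are given as control, then metformin. H3K4me3 sharing (77.3% and 67.3%) became 90.3% and 78.5% at a −log10 q of 5 or more, 71.9% and 78.9% with lists of equal length, 69.0% and 56.2% when at least 50% of an interval had to be overlapped, and 80.7% and 75.9% with intervals within 1 kb merged. H3K27me3 sharing (48.3% and 46.3%) became 29.9% and 26.1% with at least 50% of an interval, 47.8% and 46.0% with merging, 41.3% and 40.3% at a mean −log10 q of 1.5 or more, 94.1% and 92.2% for intervals of 2 kb or more (61.0% and 55.7% of their length), and 56.2% and 63.6% at 5 or more. That last setting left 16 and 11 intervals (0.0111 and 0.0137 Mb), too few to rank the conditions, while 28139 and 30403 H3K4me3 intervals passed it. Limits on −log10 q were set on both lists, but the 2 kb limit for H3K27me3 sharing only on the list counted. Against the full other list, H3K27me3 intervals of 1.5 or more were shared at 57.5% and 56.8%, so the fall at 1.5 came from shortening the other list. Broad H3K4me3 domains (1236 and 1595) numbered 7403 and 8772 from 2 kb upwards, with 86.7% and 72.4% shared, and 5627 and 6778 with merging, with 85.6% and 70.9% shared. The stricter threshold and the equal list length left out no broad domain, so they test nothing there. Intervals with both marks (1408 and 2432) numbered 652 and 1259 among H3K4me3 intervals of 5 or more (2.32% and 4.14%), and made up 1.92% and 3.29% when at least 200 bp had to overlap. Metformin had the larger H3K4me3 coverage at 5 or more, the larger number of broad domains from 2 kb and with merging, and the larger overlap of the marks under both of its settings. With the longer list trimmed to the lines of the shorter, metformin H3K4me3 had fewer intervals (40562 against 50585) but covered 51.4 Mb against 49.4 Mb, a ratio of 1.04 in place of 1.12, and the H3K27me3 ratio stayed at 1.09. The equal lists have equal numbers of lines, not of intervals, and leave out only the lowest metformin values. That construction lowers the control share and the metformin interval number and raises the metformin share, so the order of the conditions there says nothing about H3K4me3 sharing. The order also turned for H3K27me3 sharing at 5 or more. Of the values recomputed, 38 moved and 34 stayed within the counting interval of a share or within 1.5 times a count. The 34 include values that could not move, so they do not measure stability. Among these are the broad domains under the 2 settings that left none out, the control lists at equal list length and the exclusion on chromosome 2. Depth is unknown, so the larger metformin lists cannot be separated from deeper sequencing or a more efficient precipitation. For H3K27me3 they also cannot be separated from a difference in calling, since the smallest gap and the shortest interval differed between its lists.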

Other observations

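H3K27me3 was spread very unevenly over the chromosomes in control cells. It covered 81.6 kb per Mb on chromosome 20, 47.8 on chromosome 12, 43.6 on chromosome 19 and 43.1 on chromosome 17, but 5.14 on chromosome 13 and 4.97 on the X chromosome. The metformin list gave 87.7 kb per Mb on chromosome 20 and 5.59 on the X chromosome. H3K4me3 was densest on chromosome 19 (58.3 kb per Mb in control, 68.8 after metformin) and, among chromosomes 1 to 22 and X, sparsest on chromosome 13 (5.85 and 6.50). The 3 densest H3K27me3 bins of control cells were 2 to 3, 5 to 6 and 4 to 5 Mb of chromosome 12, with 615, 561 and 507 kb covered, and the metformin list held 612, 553 and 538 kb there.

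The test of fragments carried over between libraries and the comparisons across chromosomes were chosen after the results were seen. The other tests were set before their results, on patterns that had been noticed in the same data.

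Both marks covered more sequence after metformin, with the highest ratios to control on chromosome 22 (1.23 for H3K4me3 and 1.22 for H3K27me3). Across 23 chromosomes the H3K4me3 and H3K27me3 ratios went together (Spearman rho 0.591, Pearson r 0.668, or r 0.585 without chromosomes 16 and 22), with chromosomes not being independent replicates; the other relations looked at were of H3K4me3 density in control with the H3K4me3 ratio (rho 0.308) and with the H3K27me3 ratio (rho 0.113, or 0.00909 without chromosomes 18 and 22). A bias shared by the treated libraries, or by an input used for both marks, could give this, but over 1 Mb bins it stays open: in 3 equal classes of bins from the lowest to the highest control H3K4me3 coverage, the rho of the 2 changes was 0.00159, 0.133 and 0.117, and over all bins it was 0.0781, within the range of -0.0119 to 0.0805 that held 95% of values with bins permuted within chromosomes. The treated H3K27me3 library was tilted toward regions dense in H3K4me3. The H3K27me3 change and control H3K4me3 coverage had a rho of 0.213 over 1599 bins (-0.0236 to 0.0659 with permuted bins), against 0.113 over whole chromosomes. Ranges from permuted single bins take no account of likeness between neighbouring bins and do not measure variation between libraries. Median H3K27me3 ratios were 1.05, 1.11 and 1.19 from the lowest to the highest class. The median log2 change of H3K4me3 showed no steady rise over these classes (0.164, 0.124 and 0.158). The tilt thus describes where the H3K27me3 change lay. Whether it bears on why the ratios of the marks went together across chromosomes was not decided. There, control H3K4me3 density and the H3K4me3 ratio had a Pearson r of 0.370. Without chromosomes 16 and 22 it was 0.489, with a rho of 0.247. For the H3K27me3 ratio r was 0.133, or 0.102 without chromosomes 18 and 22. A tilt of this kind may be technical (fragment GC content, digestion, input) or an effect of metformin, and with 1 library per condition these cannot be told apart.

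Sequence covered by both marks was 2.11 times as long after metformin. Length added without regard to the other mark would have raised the observed and the random overlap alike, and this was not so. The observed overlap was 0.341 of the random one in control and 0.580 after metformin, a ratio of 1.70 (1.25 to 2.15 over the range of the random draws). Random placement does not model lists that grow at interval edges or weak sites. The overlap of the marks was not recomputed with lists of equal length, so list length is not excluded. H3K4me3 fragments carried over into the treated H3K27me3 library, as the whole cause, should have given the highest share at the strongest H3K4me3 sites, and did not: of the control H3K4me3 intervals with a −log10 q of 50 or more, 0.241% (4 of 1659, 95% interval 0.0657 to 0.616) were overlapped by metformin H3K27me3, against 3.49% to 4.76% in the classes under 20. Such carry-over also cannot act on the pairing of metformin H3K4me3 with control H3K27me3, which holds no treated H3K27me3 list. That pairing gave 0.738 Mb against 0.514 Mb within control, so in these lists it argues against carry-over as the whole cause. Carry-over as part of the cause is not excluded. The share at 50 or more was also lowest with control H3K27me3 (0.301%, 5 intervals). The number overlapped by metformin H3K27me3 was 1.48 times that by control H3K27me3 at 20 to 50 and 1.41 times at 10 to 20. Under 10 it was 1.15 to 1.29 times (differences of 0.437, 1.02 and 0.517 to 0.865 percentage points). Lower specificity of a precipitation, the tilt described above and an effect of metformin also stay open and were not tested for this pattern.

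The uneven H3K27me3 coverage of chromosomes may follow DNA copy number in this aneuploid line, since an extra copy could lift weak regions over the calling threshold. It should then also lift the values of H3K4me3 sites, but control H3K27me3 coverage and the median −log10 q of shared H3K4me3 intervals of 1 kb or more had a rho of 0.0889 over 1679 bins, between the limits set in advance for and against. Over the 23 chromosomes the rho was 0.464. The input libraries were not analysed here, and no biological explanation was tested.

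The stretch of chromosome 2 between 92 and 93 Mb, with the highest H3K27me3 values of both lists (53.0 and 49.9), also held 1 H3K4me3 interval in each condition. It held 16 of 85579 control and 13 of 85952 metformin H3K27me3 intervals. Without it H3K27me3 sharing stayed at 48.3% and 46.3%, but so few intervals could not have moved either mark's sharing beyond its counting interval. Leaving it out therefore tests nothing about sharing.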
